A study of Canis lupus familiaris with 4 samples.

How the data were processed

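Genomic DNA of the canine diffuse large B-cell lymphoma line CLBL-1 and of CLBL-1 8.0, a doxorubicin-resistant derivative kept in medium with 8 µM doxorubicin, was measured by MethylCap-seq. In this assay a methyl-binding domain protein captures methylated DNA fragments, which are then eluted and sequenced. Per the labels' protocols, each line gave a low salt eluate, described as low-methylated, and a high salt eluate, described as medium to high-methylated, sequenced as paired-end reads on an Illumina NovaSeq. The 4 libraries therefore form 4 groups of 1 library each, with no replicates. BWA and MACS2 are named for the CanFam3.1 assembly, per the submitters' processing notes, with versions, roles and settings not given in the sources used here.

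The deposited data used here are 1 region table per cell line and a short summary sheet of region numbers per location class. Each row of a table holds a region's coordinates, its nearest gene, the signed distance from the region start to that gene's transcription start, its location class, flags for CpG island, CpG island shore, enhancer, transcription start and promoter, and a fold enrichment. The fold enrichment is the authors' linear ratio for each region, per the file headers, and ranged from 2.00 to 32.1. What background it is relative to, and whether the low and high salt libraries of a line were pooled before calling, is not given in the sources used here. The tables do not separate the eluates, so the planned comparisons of elution fractions and of values per library were not run. The summary sheets call the regions DMR without naming what they differ from. They are treated here as regions enriched by the capture in 1 line, and the fold was used to describe, rank or filter regions within a list. The exception is a stricter alternative that keeps regions above the pooled median fold of both lists. In 71549 one-to-one pairs of shared regions the median log2 ratio of the folds, CLBL-1 8.0 over CLBL-1, was -0.27, and it was -0.28 in islands or shores, so this limit takes more from CLBL-1 8.0. Coordinates are printed as the tables give them, on CanFam3.1. Whether the tables count positions from 0 or from 1 is not stated in them.

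Read numbers per library are not part of these tables, so the depth of each library is unknown and limits on detection cannot be given. A region missing from a list is therefore not evidence of unmethylated DNA. Some information on the background remains in the fold values. In CLBL-1, 18.4% of the folds were whole multiples of 0.339, and in CLBL-1 8.0, 24.8% were whole multiples of 0.317, against 0.0077% and 0.0068% for shifted steps, counting a fold as whole within 2e-05. If the fold is pileup plus 1 over background plus 1, as MACS2 computes it, regions on such a step have a genome-wide rather than a local background, of 1.95 and 2.16 fragments. That formula is an assumption about the authors' settings.

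Region numbers in the tables equalled the authors' summary in every class except gene body, where the authors' deposited summary gave 42641 against 42639 counted in CLBL-1 and 67648 against 67642 in CLBL-1 8.0. The differences of 2 and 6 equal the number of rows with displaced cells, which were kept as regions and given no gene. The promoter flag matched a window of 3000 bp upstream of the transcription start for 99.99% of the regions with a gene in each list.

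Regions were counted as shared when they had at least 1 bp in common (bedtools 2.31.1). As the level without a relation, regions were placed at random on their own chromosome 100 times. Shares carry Wilson 95% intervals and differences of shares carry Newcombe 95% intervals (statsmodels 0.14.6). These cover counting error only, since regions are not replicates and neighbouring regions are not independent. No p-value is given, because every comparison sets single libraries of 1 line against those of the other. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

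A gene had a promoter region when a region assigned to it carried the promoter flag. A region on the edge between neighbouring genes can be assigned to different genes in the 2 tables, so genes listed in 1 line only were also examined by whether any of their promoter regions met a region of the other list. Before the data were examined, 16 gene lists were fixed. Each list's share of members with a promoter region was placed as a percentile among 10000 random lists of the same size, drawn from 17395 named protein-coding symbols of the dog RefSeq annotation on UU_Cfam_GSD_1.0, which was used for names only. Of 14273 named genes in the tables, 13458 matched such a symbol. Matching on gene length was planned but not run, because a CanFam3.1 annotation was not used here. Percentiles that count any region of a gene can therefore reflect gene length. The change in a list (members with a promoter region in CLBL-1 8.0 minus those in CLBL-1) was placed in the same way, which gives 48 percentiles, of which chance alone would put some beyond 2.5 or 97.5. The percentile of a change also depends on the share a list starts from in CLBL-1, since members already listed there cannot be gained. On simulated lists of 40 genes, 40 lists per setting, percentile 97.5 was exceeded by 2.5% of lists with the background share, 45.0% with 1.5 times that share and 97.5% with 2 times that share. These simulations cover the share only, with fewer random lists than the main count. The change between the lines was not simulated.

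Named genes followed a rule fixed before the data were examined. It takes, per line, the 10 promoter regions of highest fold with a gene symbol whose gene has no promoter region in the other list and whose region meets none there. It adds at most 4 members per gene list with a promoter region in 1 line only, ranked by fold, and a few genes whatever their values, among them ABCB1, TOP2A, PAX5 and DNMT3B. Some genes that the rule takes are not reported here. Further examples within lists, families of gene symbols, and the windows of chromosome 14 with the genes named for them were chosen after their values were seen, except genes that the rule takes. Alternatives were a stricter fold, merged regions, other overlap limits, chromosomes left out, lists of equal length, promoters by position, regions near a transcription start, any region of a gene, and a smaller background.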

Results

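The methylated DNA captured from CLBL-1, a canine diffuse large B-cell lymphoma line, was compared with that of its doxorubicin-resistant derivative CLBL-1 8.0 by MethylCap-seq. Each line had 1 low salt and 1 high salt library, and each line's regions are reported as a single list. The read depth of the libraries is unknown, and no difference below has a replicate check. Region coordinates refer to CanFam3.1, and fold enrichments are the authors' values within each list.

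The CLBL-1 8.0 list was longer than the CLBL-1 list on 38 of the 40 chromosomes, the mitochondrial one included. CLBL-1 had 82247 regions covering 53.1 Mb and CLBL-1 8.0 had 123421 regions covering 67.0 Mb, a ratio of 1.26 in covered length. Regions of CLBL-1 8.0 were shorter, with a median of 428 bp against 542 bp. Regions shared by both lists had medians of 569 bp and 572 bp, and the regions of CLBL-1 8.0 alone had 315 bp. The median fold was 5.95 (interquartile range 4.07 to 9.69) in CLBL-1 and 5.06 (3.81 to 6.73) in CLBL-1 8.0. Among chromosomes, 14, 27, 6 and 12 had the highest ratios of CLBL-1 8.0 to CLBL-1 regions, at 2.32, 2.14, 1.98 and 1.90. The ratio was 1.15 on chromosome X and 0.918 on chromosome 36. Above the pooled median fold of both lists, the numbers were 47206 and 55627.

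Nearly all CLBL-1 regions were also present in CLBL-1 8.0, while many CLBL-1 8.0 regions had no counterpart. Of the CLBL-1 regions, 74857 (91.0%) met a CLBL-1 8.0 region, against a mean of 6.58% after random placement. Of the CLBL-1 8.0 regions, 75986 (61.6%) met a CLBL-1 region, against 4.43% after random placement. The remaining 7390 CLBL-1 regions had a median fold of 3.53, below the 6.38 of shared regions in that list. The remaining 47435 CLBL-1 8.0 regions had a median fold of 4.75, against 5.41 for shared regions. With as many regions in both lists, which leaves out CLBL-1 8.0 regions below a fold of 4.23, the share of CLBL-1 regions met fell to 62.4%.

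The genomic context of the lists differed mainly in CpG density. Regions outside CpG islands and shores made up 46.8% (95% interval 46.5 to 47.2) of the CLBL-1 list and 62.5% (62.3 to 62.8) of the CLBL-1 8.0 list, a difference of 15.7 percentage points (15.2 to 16.1). Their numbers were 38530 and 77177. CpG island regions numbered 11466 and 12640, and island shore regions 32291 and 33638, so that their shares were lower in CLBL-1 8.0, at 10.2% against 13.9% for islands and 27.3% against 39.3% for shores. Promoter regions were 12.2% of the CLBL-1 list and 10.1% of the CLBL-1 8.0 list, a difference of -2.08 percentage points (-2.36 to -1.80). Regions at transcription starts were nearly equal in number, at 4215 and 4244. Introns held 37.4% and 42.1% of the regions, and annotated enhancers 5.04% and 5.07%, whose intervals overlapped.

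**Figure D1:**
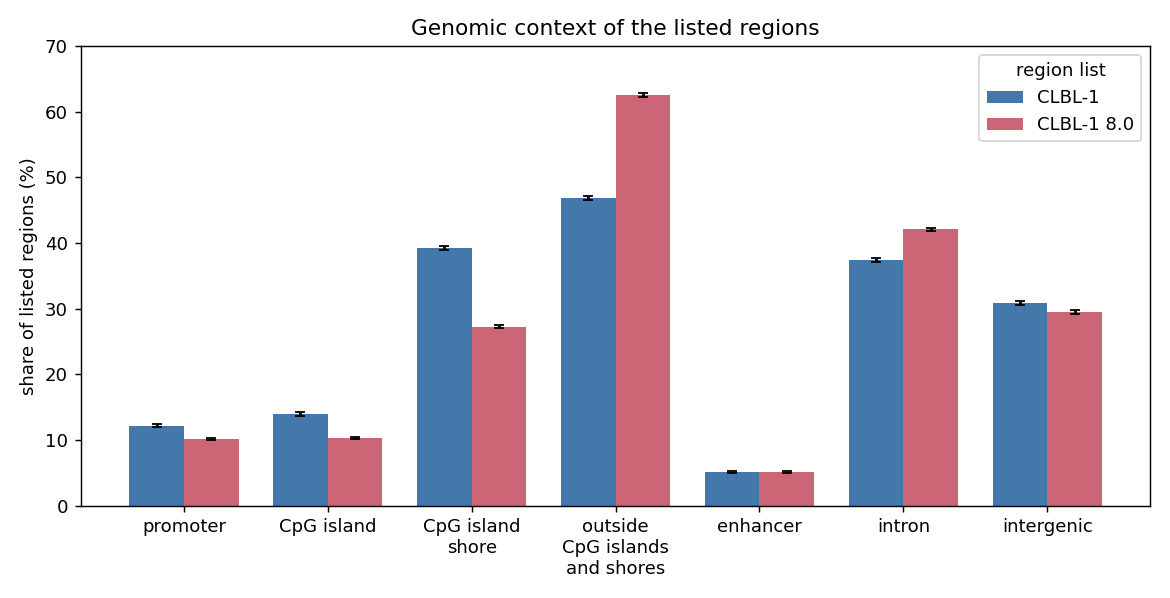
Share of each cell line's listed regions (percent, vertical axis) in 7 classes of genomic context, with CLBL-1 in blue and CLBL-1 8.0 in red. Error bars are Wilson 95% intervals for counting error, and classes can overlap. The share outside CpG islands and shores was 46.8% in CLBL-1 and 62.5% in CLBL-1 8.0.

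Regions found in 1 list only had different contexts in each line. Among the CLBL-1 8.0 regions with no CLBL-1 counterpart, 88.7% (88.4 to 89.0) lay outside CpG islands and shores and 1.69% (1.58 to 1.81) met an island. Among the CLBL-1 regions with no counterpart, 48.2% (47.1 to 49.4) lay outside islands and shores and 21.0% (20.1 to 21.9) met an island. In the shared regions, the share outside islands and shores was 46.7% of the CLBL-1 regions and 46.2% of the CLBL-1 8.0 regions.

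Promoters with a region were more numerous in CLBL-1 8.0. A promoter region was listed for 8489 genes in CLBL-1 and 10474 genes in CLBL-1 8.0, of which 7726 were listed in both, 763 in CLBL-1 only and 2748 in CLBL-1 8.0 only. Of the 763 genes, 274 (35.9%) had promoter regions that met no CLBL-1 8.0 region at all, and of the 2748 genes, 2241 (81.6%) met no CLBL-1 region. With the promoter window placed by position, 443 genes were in CLBL-1 only and 2412 in CLBL-1 8.0 only. With lists of equal length, the numbers were 2327 and 2036, where only CLBL-1 8.0 lost regions of low fold.

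The promoter regions of highest fold that were listed for CLBL-1 and absent from CLBL-1 8.0 included a pair of neighbouring kallikrein genes, which encode secreted serine proteases. KLK7 had a region at chromosome 1, 105890885 to 105891387, 321 bp upstream of its transcription start, with a fold of 16.4. KLK6 had one at 105900472 to 105901102 on the same chromosome with a fold of 9.84. Both lay outside CpG islands and shores. RPS29, a ribosomal protein gene, had a fold of 15.9 at a CpG island 78 bp upstream of its start (chromosome 8, 26223658 to 26224004). IQCB1 (11.5), UQCRH (8.48) and GLB1L3 (8.05) also had island regions, as did ARRDC1, whose fold lay between those of RPS29 and IQCB1. LEPR, the leptin receptor gene (9.50), and SMARCAD1, a chromatin remodeller (8.82), had shore regions. UHRF1, which encodes the factor that guides DNMT1 to newly replicated DNA, had a fold of 8.21 for a region 1371 bp upstream (chromosome 20, 54891140 to 54891617).

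In CLBL-1 8.0 the corresponding promoter regions of highest fold were mostly at island shores. VPS72, a subunit of histone-exchange complexes, had a fold of 12.2 (chromosome 17, 60254962 to 60255362, 2639 bp upstream). SRI, which encodes the calcium-binding protein sorcin, had a fold of 11.3 (chromosome 14, 14275831 to 14276701), and DMTF1, a transcription factor gene, 10.3 (chromosome 14, 13335293 to 13336060). Both lie in a stretch of chromosome 14 with many more regions in CLBL-1 8.0, described further on. KBTBD8 (11.1), LMBR1L (10.4), FBXO4 (10.1) and GTF2F2 (9.50) also had shore regions. RMND5A (9.50) had an island region, while COPG2 (9.81) and LEPROTL1 (9.50) had regions outside islands and shores.

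Genes related to the drug were examined through lists of drug transporters and anthracycline metabolism. Of 26 drug transport genes, 7 had a promoter region in CLBL-1 and 13 in CLBL-1 8.0. The 6 genes listed in CLBL-1 8.0 only included ABCB1, ABCB10, ABCC1, ABCC4 and MVP, and none was listed in CLBL-1 only. This change lay at percentile 98.7 of random lists, but at 96.8 when the genes of chromosome 14 from 13 to 17 Mb were taken out of the list and the background. It did not pass the upper limit in 5 of 6 alternatives, with values from 42.9 to 96.8. ABCC4, an efflux transporter gene, had the highest fold of the 6, at 7.60 (chromosome 22, 46014113 to 46014546, in an island). ABCB10 (7.41) is not a clear case, since a CLBL-1 region met the same window. MVP, the major vault protein gene, had a fold of 5.00. Of 33 anthracycline metabolism and redox genes, 7 and 11 had a promoter region, with GSTP1 (4.16), RAC2 (4.08), AKR1A1 (3.48) and PRDX2 (2.55) in CLBL-1 8.0 only, a change at percentile 81.6.

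ABCB1 encodes P-glycoprotein, an efflux pump for which doxorubicin is a substrate. No region was listed for it in CLBL-1 and 33 were listed in CLBL-1 8.0, between positions 13640514 and 13856083 of chromosome 14. Of these, 29 were intronic, 2 downstream, 1 coding and 1 in the promoter. The promoter region (13855787 to 13856083) began 2958 bp upstream of the transcription start, lay outside islands and shores and had a fold of 2.72, while the highest fold in the gene was 11.8.

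These regions belong to a stretch in which the lists differed more than in any other 1 Mb windows. The 4 windows of chromosome 14 from 13 to 17 Mb held 41 CLBL-1 regions and 770 CLBL-1 8.0 regions, and had the highest log2 ratios of 2343 windows, from 3.36 to 4.15. The median window had a log2 ratio of 0.58 and the 99th percentile was 1.89. All 41 CLBL-1 regions there met a CLBL-1 8.0 region. In CLBL-1 8.0, 96.6% of the 770 regions lay outside islands and shores. Region numbers went from 4 to 99 in CDK14, from 6 to 89 in ZNF804B, from 2 to 66 in ADAM22, from 2 to 37 in RUNDC3B and from 1 to 26 in ABCB4, a phospholipid transporter gene next to ABCB1. A second stretch of chromosome 14, from 3 to 9 Mb, held 193 and 619 regions. Outside both stretches the density on this chromosome was 21.5 regions per Mb in CLBL-1 and 33.3 in CLBL-1 8.0.

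**Figure D2:**
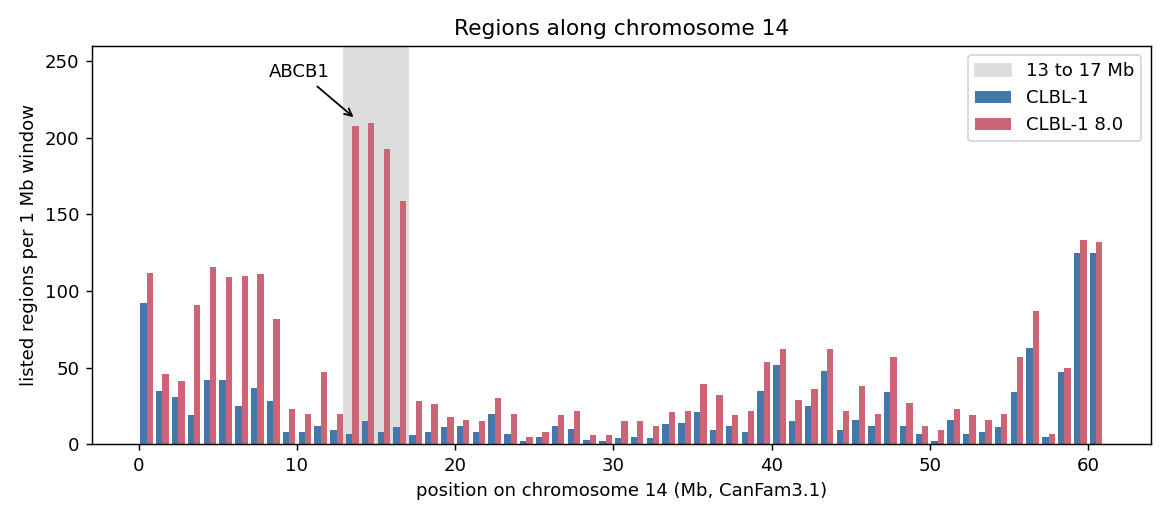
Number of listed regions (vertical axis) in 1 Mb windows along chromosome 14 (horizontal axis, Mb on CanFam3.1), with CLBL-1 in blue, CLBL-1 8.0 in red and the stretch from 13 to 17 Mb shaded. The shaded windows held 41 CLBL-1 and 770 CLBL-1 8.0 regions, and the arrow marks the window with ABCB1.

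Of 39 apoptosis genes, 6 had a promoter region in CLBL-1 (15.4%) and 13 in CLBL-1 8.0 (33.3%), at percentiles 2.92 and 38.6. Against genes with any region, the list lay at percentile 0.60 in CLBL-1, and above the pooled median fold at 4.8. Counting any region of the gene, it lay at percentiles 67.9 in CLBL-1 and 95.2 in CLBL-1 8.0. The 7 genes listed in CLBL-1 8.0 only included BCL2L2, CASP2, CASP9, DIABLO, FAS and MCL1. This change lay at percentile 97.6 of random lists, and did not pass the upper limit in any of 6 alternatives, with values down to 79.1. MCL1, which encodes an anti-apoptotic BCL2 relative, had a fold of 8.53 at an island shore 2058 bp upstream (chromosome 17, 59765169 to 59765668). BCL2L2 had 5.88 and DIABLO, an antagonist of inhibitor of apoptosis proteins, 4.43, while the CASP2 window (8.19) was also met by a CLBL-1 region.

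Of 41 topoisomerase and DNA damage genes, 7 and 9 had a promoter region, at percentiles 4.63 and 3.08. Counting any region of the gene, the list lay at percentiles 64.3 and 99.9, with 12 genes in CLBL-1 8.0 only and a change at percentile 99.5. Gene length, which was not matched, can affect this count. Against genes with any region the list lay at percentiles 0.585 and 0.20, and with promoters by position at 1.88 in CLBL-1 8.0. MDM2, a ubiquitin ligase gene (6.96), and XRCC5 (3.48) were listed in CLBL-1 8.0 only and XRCC1 (4.41) in CLBL-1 only. TOP2A, the topoisomerase that doxorubicin poisons, had 1 region downstream of the gene in each line, with folds of 5.43 and 5.47, and no promoter region.

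Homeobox and developmental genes had the largest share of promoter regions among the 16 lists in both lines, counting all listed regions. Of 123 homeobox and developmental transcription factor genes, 96 (78.0%, 69.9 to 84.5) had a promoter region in CLBL-1 and 93 (75.6%, 67.3 to 82.3) in CLBL-1 8.0, where the background shares were 28.8% and 35.7%. Both exceeded all random lists. Counting only regions above the pooled median fold, the list fell to percentile 87.4 in CLBL-1 and to percentile 0.68 in CLBL-1 8.0, and with lists of equal length 39 members, percentile 82.5, had one in CLBL-1 8.0. The change of -3 genes lay at percentile 0.085 of random lists, and from 0 to 0.04 in 6 alternatives. Only 27 members had no promoter region in CLBL-1, which leaves few to gain. The change was -15 above the pooled median fold and -57 with lists of equal length. Both limits take more from CLBL-1 8.0, whose shared regions had lower folds, so these values do not show a change in promoters. HOXD9 (7.70) and FOXF1 (4.66) were listed in CLBL-1 only and EN2 (4.81) in CLBL-1 8.0 only, but each region met one of the other list. DLX5 (5.30) was listed in CLBL-1 only and met none.

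Promoter regions were also frequent among 27 epithelial and stromal markers (18 and 19 genes), 50 ion channel and synaptic genes (32 in both lines), 51 Wnt, Notch and TGF-beta genes (30 and 32) and 39 cell adhesion genes (22 and 24), each above percentile 99.9 in both lines. Above the pooled median fold, the Wnt, Notch and TGF-beta list fell to percentiles 78.8 and 61.8, and counting any region of the gene the epithelial and stromal markers lay at 94.1 in CLBL-1 8.0. KRT5, KRT14 and CDH1, all epithelial genes, had promoter regions in both lines, with folds of 8.27, 11.5 and 9.66 in CLBL-1. PDGFRB (4.15), a stromal receptor gene, was listed in CLBL-1 8.0 only. KCNMA1 (7.16), a potassium channel gene, was listed in CLBL-1 only. SMAD3 (4.73), WNT3A (4.29) and LRP6 (4.04) were listed in CLBL-1 8.0 only, and TGFB3 (4.08) in CLBL-1 only. Among adhesion genes, CDH23 (5.72), ITGB1 (4.75) and CD58 (4.75) were listed in CLBL-1 8.0 only, and the CNTNAP5 region (14.6), in CLBL-1 only, met a CLBL-1 8.0 region.

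**Figure D3:**
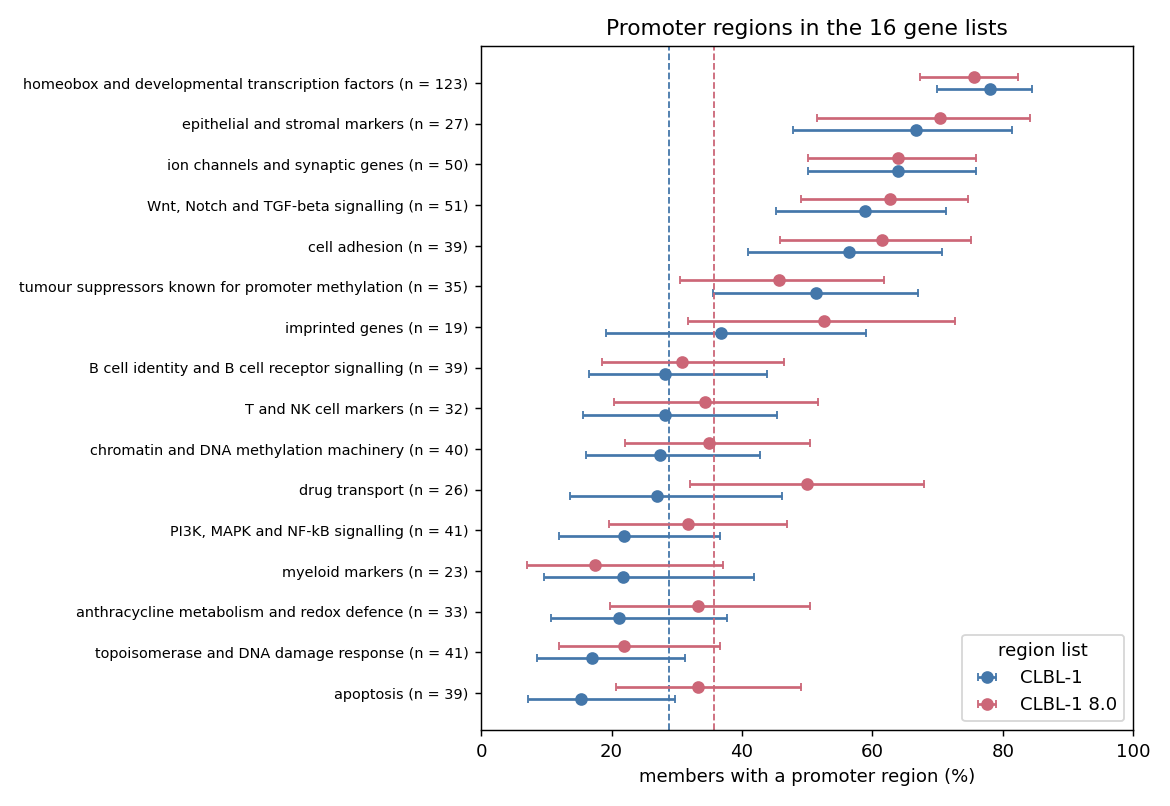
Share of each gene list's members with a promoter region (percent, horizontal axis) for 16 lists, with CLBL-1 in blue and CLBL-1 8.0 in red, and n the number of members. Bars are Wilson 95% intervals, and dashed lines are the shares of the background genes, 28.8% and 35.7%. The homeobox list had the highest share in both lines, 78.0% and 75.6%.

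Of 35 tumour suppressors known for promoter methylation, 18 had a promoter region in CLBL-1 and 16 in CLBL-1 8.0, at percentiles 99.7 and 88.1. With promoters by position, 19 had one in each line, and the list passed the upper limit in CLBL-1 8.0 as well. The change of -2 genes lay at percentile 1.1 of random lists. In 6 alternatives it lay from 0.205 to 8.69, the last by position. SFRP1, SFRP4, SFRP5, SOCS3 and ID4 were listed in CLBL-1 only, with folds of 12.1 for SFRP4 and 17.4 for SFRP5, but the regions of all 5 met a CLBL-1 8.0 region. CDKN2B and RASSF1, both with a fold of 5.38, and ABCB1, which belongs to this list as well, were listed in CLBL-1 8.0 only and met no CLBL-1 region.

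Shares of B cell, T cell and NK cell genes were close to the background. Of 39 B cell genes, 11 and 12 had a promoter region, at percentiles 47.5 and 26.1. PRDM1, the regulator of plasma cell differentiation (4.28), was listed in CLBL-1 8.0 only. POU2AF1 (9.78) was listed in CLBL-1 8.0 only, although its region met a CLBL-1 region. PAX5, the B cell identity factor, had 2 promoter regions in each line and 16 and 24 regions in all. Of 32 T and NK cell markers, 9 and 11 had a promoter region, with CD4 (4.93) and LCK (3.06) in CLBL-1 8.0 only. Of 23 myeloid markers, 5 and 4 had one, at percentiles 24.0 and 2.99 (1.99 in CLBL-1 8.0 counting any region), with ITGAM (5.38) and CSF3R (3.94) in CLBL-1 8.0 only and CD68 (3.67) in CLBL-1 only. FCGR1A (10.9), listed in CLBL-1 only, had its window met by CLBL-1 8.0 as well.

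The changes in the lists of chromatin, PI3K, MAPK and NF-kB, and imprinted genes lay at percentiles 54.9, 70.5 and 86.7. Of 40 chromatin and DNA methylation genes, 11 and 14 had a promoter region, at percentiles 44.4 and 46.6, or above percentile 99.9 in both lines counting any region of the gene. Besides UHRF1, HDAC2 (7.68) was listed in CLBL-1 only, with a region that met CLBL-1 8.0, and KMT2A (5.70) and EP300 (4.43) were listed in CLBL-1 8.0 only. DNMT3B had 2 and 3 regions, none in the promoter. Of 41 PI3K, MAPK and NF-kB genes, 9 and 13 had a promoter region, at percentiles 17.9 and 30.5. Against genes with any region the list lay at 3.2 and 5.5, and counting any region of the gene at 99.9 in CLBL-1 8.0. The any-region percentiles of the chromatin and the PI3K, MAPK and NF-kB lists were not matched on gene length, which can affect them. NFKBIA, NFKB2 (both 5.70), MAPK8 (5.06) and RPTOR (4.51) had a promoter region in CLBL-1 8.0 only, RPTOR by a region that met a CLBL-1 region. Of 19 imprinted genes, 7 and 10 had one, with KCNQ1 (4.12) in CLBL-1 8.0 only. IGF2R (5.19) and SGCE (4.83) were also listed in CLBL-1 8.0 only, but their windows were met by CLBL-1.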

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

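No paired analysis was possible because each group has 1 library and no result comes from a test. The eluates alone, a CanFam3.1 annotation and lists matched on length were not run, and no unplaced scaffold was listed. The equal-length lists, chromosomes 6, 12, 14 and 27 or the 13 to 17 Mb stretch left out, promoters by position, starts within 1000 bp and the smaller background were chosen after seeing the data. In every alternative run, CLBL-1 8.0 kept the smaller promoter share and the larger share outside CpG islands and shores.

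Above the pooled median fold, by construction fewer regions, there were 47206 CLBL-1 and 55627 CLBL-1 8.0 regions, 75.2% and 64.0% shared, context differences of -1.80 points for promoters and 14.4 outside islands and shores, 1335 and 1590 genes in 1 line only, and 3 lists beyond the upper percentile limit in CLBL-1 8.0 against 5 in the main count. The homeobox list in CLBL-1 8.0 fell there from above all random lists to percentile 0.68. With equal lists, which leave out low folds in CLBL-1 8.0 alone, 62.4% of each were shared, the differences were -1.31 and 21.8 points, and 2327 genes were in CLBL-1 only. Shares were 92.1% of CLBL-1 after merging, 84.9% and 56.6% for overlap of at least 50% of both, and 94.6% and 65.9% within 1000 bp. Without chromosomes 6, 12, 14 and 27 they were 90.7% and 63.8%, with 14.5 points outside islands and shores. Of CLBL-1 8.0, 61.1% was shared without chromosome X and the mitochondrion and 61.9% without the chromosome 14 stretch. Counting any region of a gene gave 465 and 4421 genes in 1 line only, and promoters by position 443 in CLBL-1 only. Above each list's own median fold, also chosen after seeing the data, the differences were -2.37 and 14.9 points. Within 1000 bp of a start the promoter difference was -2.51 points. Except where the construction shows it, the cause was not tested. Of 288 list percentiles under alternatives, 256 stayed on their side of both limits, 17 no longer passed, 14 newly passed and 1 was reversed. The reversed percentile was that of the homeobox list in CLBL-1 8.0 above the pooled median fold. Of 74 named genes, 26 stayed in 1 line only counting any region of a gene, 44 above the median fold, 64 with equal lists and 66 by position. Gene lists were not run without whole chromosomes, because genes with no region have no chromosome here. Unknown depth limits every count, because a deeper library lists more regions.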

Other observations

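The families of gene symbols and the genes described here, and the tests of extra DNA and of loss on chromosome 14, were chosen after seeing the data. Among 13 families, with 39 percentiles, olfactory receptors stood lowest, with a promoter region for 4 of 702 genes in CLBL-1 and 6 in CLBL-1 8.0, fewer than in any random list. Members were matched by symbol from the annotation of another assembly, so a gene named otherwise in the region lists counts as without a region. Whether this lowered the count of any family was not tested. Chemokines and their receptors were also low, with 4 and 8 of 44 genes, at percentiles 0.13 and 0.66. Potassium channels were high, with 49 and 54 of 94 genes, above all random lists, and collagens had 24 and 25 of 43.

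The genes with the most regions in CLBL-1 included GRID1, a glutamate receptor gene, and their numbers were similar in CLBL-1 8.0. CSMD1 had 148 and 157 regions, GRID1 122 and 117, and ZNF536 123 and 108. Outside the 13 to 17 Mb stretch, the largest rises were in AUTS2 (23 to 72), EXOC6B (6 to 54), EXOC4 (9 to 53) and PLXNA4 (49 to 92). SND1, also on chromosome 14, went from 1 to 31.

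The values argue against 2 technical accounts of the stretch of chromosome 14 around ABCB1. These are the longer list as the whole account and complete loss of the locus in CLBL-1. With lists of equal length the lowest log2 ratio of its 4 windows was 2.50, above the 99th percentile of 1.69 elsewhere. These windows were picked for the highest ratios in the same lists, so their rank is no independent support. That cut kept 51.7% of the CLBL-1 8.0 regions of the stretch against 66.6% of all. It still left 398 there, against 41 of CLBL-1. The longer list alone therefore does not account for the stretch. CLBL-1 had 10.25 regions per Mb there (exact Poisson 95% interval 7.36 to 13.9), above the 5th percentile of 2.80 on the rest of the chromosome. The windows of that rest had a median of 12 and a mean of 22.7 CLBL-1 regions. The Poisson interval treats regions as independent. The CLBL-1 regions listed there argue against complete loss of the locus in CLBL-1, but they were known before this limit was set. So low a limit cannot detect the loss of some copies, which stays open. A candidate explanation is more DNA of the locus in CLBL-1 8.0, since only 0.672% of its regions outside islands and shores were on the genome-wide background step, below the 5th percentile of 7.27% in 1420 other windows and below the 33.3% of the stretch from 3 to 9 Mb. In CLBL-1, 9 of the 25 such regions in the stretch (36%) were on the step of that line. This does not tell more DNA from denser methylation in CLBL-1 8.0, since either could raise the local background there. More DNA is a hypothesis that rests on an assumed formula for the fold. Dense windows had low shares elsewhere as well. The median was 11.6% in 162 other windows with at least 80 regions outside islands and shores, against 38.7% in the 1420. Of these 162 windows, 2 had a lower share than the stretch, so dense methylation of the stretch, or its change under doxorubicin, stays open.

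The larger share of CLBL-1 8.0 regions outside CpG islands and shores was set against 3 technical explanations. The difference was 14.4 percentage points above the pooled median fold and 14.9 above each list's own median, chosen after seeing the data. It was 14.5 without chromosomes 6, 12, 14 and 27. Each value was above 5 points, a limit set before the other values were seen. This argues against regions of low fold and against those chromosomes as the whole account. Regions near the calling limit stay open, because the caller's settings are not given and a cut on fold may leave such regions in. The median fold was also higher outside islands and shores than in them, at 6.29 against 5.54 in CLBL-1 and 5.06 against 4.61 in CLBL-1 8.0. With lists of equal length the difference was 21.8 points. That cut kept 73.2% of the CLBL-1 8.0 regions outside islands and shores and 55.7% of the others, so it cannot count against the longer list. The length of the list and the difference cannot be told apart here. The longer list therefore stays open, and so does a difference in depth, in capture or in the balance of the eluates, which was not tested because the tables do not separate the libraries. A difference in methylation between the lines stays open beside these.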
